A study of Tachysurus fulvidraco x Tachysurus vachelli with 6 samples.

How the data were processed

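Gene expression was measured by RNA sequencing in the second left gill of juvenile hybrid yellow catfish, a cross of Tachysurus fulvidraco females with Pelteobagrus (Tachysurus) vachellii males. The 6 gill libraries fell into 2 groups by the labels: 3 untreated controls and 3 from fish transported for 16 h. Per the labels' protocols, total RNA was isolated with TRIzol and the libraries were made with Illumina's standard preparation, with no statement on strand. The labels number the samples within each group but do not say whether a library came from 1 fish or from a pool, so the p-values measure the spread between these libraries, part of which may be technical.

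The deposited table held 25792 genes with scaffold coordinates, product names, GO and KEGG terms, and 12 columns of values, all of which were used. Per the file headers, the authors gave a count and an FPKM (fragments per kilobase of transcript, scaled to library size) for each gene and library. The submitters' processing notes name HISAT and StringTie without a version, and the genome build is not given in the sources used here. The deposited counts are whole numbers but are treated here as estimated counts, because the values 4 and 8 were several times as frequent as their neighbours in every library. In the first control library, for example, 427 genes had a value of 4 against 113 at 3 and 81 at 5, so 1 fragment seems to be worth about 4 units. The deposited FPKM values summed to between 600952 and 616602 per library. Reads of near-identical gene copies, overlapping genes and antisense partners could not be told apart with these values, and 11687 of the 20771 genes tested carried only a locus number.

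The totals ranged from 42962760 to 58495713 estimated counts per library. With about 4 units to a fragment, the number of fragments was lower than these totals by about that factor, and counting error was correspondingly larger for genes with few counts. The FPKM values in the text are the deposited ones, given as mean ± SD over the 3 libraries of a group.

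The design fixed before the data were examined assumed FPKM alone and named limma as the main test, with the clause that edgeR would be the main test if the table also held counts. It did, so transport was compared with control by edgeR 4.0.16 (R 4.3.3). The deposited counts were already whole and needed no rounding. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, scaled by TMM, and tested with the two-sided quasi-likelihood F test without covariates. P-values were adjusted by the Benjamini-Hochberg method over the 20771 genes kept, with a threshold of 0.05, and a log2 fold change of at least 1 in size marked a 2-fold change. Log2 fold changes are transport minus control. Their standard errors (SE) were derived as the size of the log2 fold change divided by the square root of the F statistic.

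Before the data were examined, 35 gene lists were fixed for gill tissue, its cell types and transport stress. Members were matched by symbol, and genes with only a locus number by product name. Each list was tested with limma's camera (version 3.58.1, two-sided, preset correlation 0.01) and adjusted over the 35 lists, beside camera with an estimated correlation and fry. A call "adjusted over the list alone" uses the gene p-values of that list only. Over-representation of the GO and KEGG terms of the deposited table among called genes used the one-sided Fisher's exact test, separately for higher and lower genes, for terms with 10 to 500 genes. The background was the 19020 tested genes with any GO term and the 8222 with any KEGG term. Principal components were computed from log2(FPKM + 1) for the genes kept for the edgeR test.

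The genes named in the report follow a rule fixed beforehand for genes with a symbol. It took the 8 largest rises and 8 largest falls among called genes with separate groups and a mean FPKM of at least 2 in the higher group, and the 4 most abundant called genes in each direction. It added up to 4 called members of each called list, up to 2 of each other list, and, for a list without a called member, the member with the smallest p. Genes of the stress response that were always to be named included nr3c1, fkbp5, hif1a, hmox1 and rhcg, while il1b, hspa5 and hsp70 matched no symbol, and others of that set are not reported here. This gave 86 genes, of which 77 were called. Genes with a locus number that are named in the text were chosen after their values were seen.

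The steps were tested on simulated counts drawn from the means and library sizes of these 6 libraries and from edgeR's dispersions. Of the 20771 genes, 200 were changed 2-fold or 4-fold, all of them with a mean FPKM of at least 1. A small set of other genes was shifted less and also counted as changed. edgeR recovered 26% of 100 genes changed 2-fold and 81% of 100 changed 4-fold, and 6.140% of its 114 calls were false. With 4 units to a fragment it recovered 28% and 80%, with 7.692% false. With 1 unit to a fragment, 31.304% of the calls of DESeq2 were false. The share was 9.009% for limma on log2(FPKM + 1). With 4 units these shares were 34.222% for DESeq2 and 5.714% for limma, the latter below that of edgeR.

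Alternatives fixed beforehand were other count filters, the replicate number as a block, DESeq2 1.42.0, limma on log2(FPKM + 1) with pseudocounts of 0.1 and 0.5, other filters and scalings, no trend, robust fitting and array weights, and leaving out each library. Scaling by library size without TMM and dividing the counts by 4 were added after the data were seen. The fit of the array weights stopped before it reached its convergence tolerance. No batch, date or lane is given by the labels. No reference genome was used here, so no sequence was examined.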

Results

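Gill transcriptomes were compared between 3 untreated juvenile hybrid yellow catfish samples and 3 samples from fish that had been transported for 16 h. The hybrid comes from T. fulvidraco mothers and T. vachellii fathers, and the tissue was the second left gill, the organ of gas exchange, ion uptake and ammonia excretion. The libraries held between 42962760 and 58495713 estimated counts each, 48543010, 58495713 and 42997762 in the controls and 42962760, 49066033 and 47307555 after transport. The 50 most abundant genes took 16.1% ± 0.608 of the counts in the controls and 15.3% ± 0.213 after transport. Of the 25792 genes in the table, 20771 had enough counts to be tested.

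The control and transport libraries lay on opposite sides of the first principal component, which held 45.0% of the variance. The second component held 21.2% and set control replicate 1 (46.9) apart from the other 5 libraries. Genes of skeletal muscle varied strongly between libraries without following the groups. Their mean level relative to all 6 libraries was 1.46 on the log2 scale in control replicate 1, -1.01 and -0.74 in the other controls, and -1.03, 0.39 and 0.92 in transport replicates 1, 2 and 3. Across genes, the Pearson correlation of log2 CPM ranged from 0.919 to 0.933 between controls, from 0.934 to 0.961 between transport libraries, and from 0.902 to 0.922 between the groups.

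**Figure D1:**
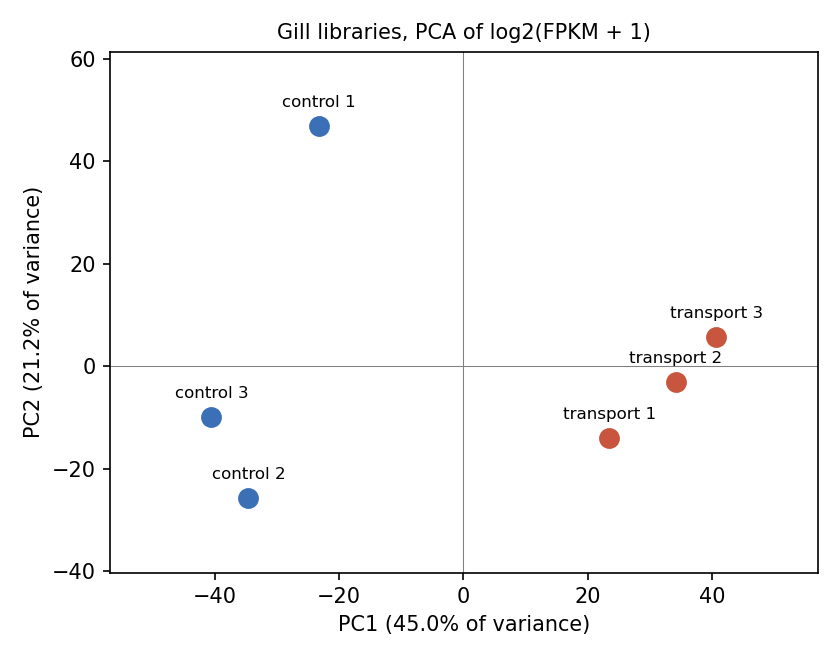
Scores of the 6 gill libraries on the first (45.0% of variance) and second (21.2%) principal components of log2(FPKM + 1), with 1 point per library. The 3 controls lie at scores of -23.3 to -40.6 on the first component and the 3 transport libraries at 23.5 to 40.8.

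The comparison asks which gill transcripts differ after 16 h of transport. Transcripts of the peptidase gene ace, which encodes angiotensin-converting enzyme (NW_020847941.1, 1849539 to 1868036), rose from 5.69 ± 0.878 to 40.1 ± 7.54 FPKM (SD, n = 3). Its log2 fold change was 2.80 (SE 0.19, edgeR adjusted p = 0.00432). The transcription factor gene irf1 (NW_020847809.1, 1575175 to 1578028), an activator of interferon and antigen processing genes, rose from 213 ± 20.7 to 607 ± 51.0 FPKM. The fibrillar collagen gene col1a2 (NW_020848070.1, 4565286 to 4582988) fell from 321 ± 73.9 to 63.3 ± 5.41 FPKM, a log2 fold change of -2.37 (SE 0.18, edgeR adjusted p = 0.00440). The glucuronidation gene ugt1a1 (NW_020847934.1, 34083 to 41378) fell from 10.99 ± 2.27 to 1.36 ± 0.335 FPKM. In all, edgeR called 1389 of the 20771 genes at an adjusted p under 0.05, 671 higher and 718 lower after transport. Of these, 675 changed at least 2-fold, 302 upward and 373 downward, and 5200 genes had an unadjusted p under 0.05. The 3 FPKM values of the groups did not overlap in 32.7% of all tested genes, against 10% by chance. The number of calls depended strongly on single libraries, with 379 without control replicate 3, 399 without transport replicate 1, 162 without transport replicate 3, and 3 without transport replicate 2. Without transport replicate 2, of the 77 called genes with a symbol named here none stayed called (edgeR adjusted p from 0.0599 to 0.187). All 1389 called genes kept their sign in that fit, and all 1389 kept an unadjusted edgeR p under 0.05. These genes had been chosen with the same remaining libraries in the fit. Of the called genes with a symbol, egln3, flt4, foxo1, grhl1, psma7, srebf1, timeless and usp18 lost their call whichever library was left out.

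The 3 genes still called without transport replicate 2 carried locus numbers and were chosen after their values were seen. LOC113647756, a transporter gene similar to SLC43A3, rose from 1.36 ± 0.304 to 23.3 ± 0.995 FPKM (log2 fold change 4.08, SE 0.19, edgeR adjusted p = 0.00248, and 0.0303 without that library). LOC113651405, annotated as similar to up-regulator of cell proliferation, rose from 1.88 ± 0.441 to 23.2 ± 1.21 FPKM. LOC113649539, annotated as an erythroblast ADP-ribosyltransferase, stood at 15.1 ± 2.94 FPKM in the controls and was listed at 0 in all 3 transport libraries.

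Among the other large rises with a symbol, the stearoyl-CoA desaturase gene scd5 went from 13.4 ± 5.27 to 53.8 ± 2.74 FPKM. The gene grem1, whose product binds and blocks bone morphogenetic proteins, went from 5.94 to 18.8 FPKM. The lipase gene pla1a (log2 fold change 2.46), the mitochondrial folate enzyme gene mthfd1l (1.91) and the glycosyltransferase gene b3gnt7 (1.71) also rose. The complement gene c7 was at most 0.07 FPKM in each control and 1.61, 3.56 and 4.49 FPKM in the transport libraries. Large falls included igfbp6, for a binding protein of insulin-like growth factors (log2 fold change -3.32), the serotonin receptor gene htr2b (-2.14), the retinoid-binding gene rbp7 (-2.15), the semaphorin gene sema3f (-2.11) and the matrix metalloproteinase gene mmp11 (-2.13). Among called genes with a symbol, the most abundant that fell was actb, cytoplasmic actin, from 6776 ± 111 to 4928 ± 383 FPKM. The chromatin protein gene hmgn2 fell from 1108 to 772 FPKM.

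Genes for heat shock proteins and their cochaperones, which fold other proteins, were higher as a group after transport. Of 41 tested, 7 rose and none fell, 13 rose when adjusted over the list alone, and 36 of the 41 log2 fold changes were positive with a median of 0.48. The mitochondrial chaperonin partners hspd1 and hspe1, neighbours on NW_020847969.1, rose from 37.9 ± 11.2 to 78.6 ± 12.7 and from 58.1 ± 12.1 to 134 ± 35.5 FPKM. The cochaperone gene dnaja4 rose from 44.8 to 76.4 FPKM and hspa14 from 6.99 to 12.5 FPKM. LOC113655582, the HSP90-alpha gene, rose from 11.7 ± 3.48 to 39.0 ± 4.31 FPKM. Camera gave the list an adjusted p of 5.59e-07, and adjusted p = 0.370 with an estimated correlation. The list's median was also 0.48 with LOC113653389, the 1 member listed at 0 in all controls, set at its lower bound. A single high value among 41 could hardly have moved that median. LOC113653389 is 1 of the 7 called members and reached only 0.377 FPKM after transport (edgeR adjusted p = 0.0459).

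Genes of the unfolded protein response, which serve folding in the endoplasmic reticulum, were higher as a group by camera. Of 33 tested, 3 rose and none fell, with 20 positive and 13 negative log2 fold changes (median 0.09). The endoplasmin gene hsp90b1 rose from 132 ± 20.4 to 209 ± 7.09 FPKM, manf from 23.8 to 43.4 FPKM, and vldlr, a lipoprotein receptor gene, from 1.85 to 5.23 FPKM. When adjusted over the list alone, 3 members rose as well. Camera gave an adjusted p of 0.0310 (adjusted p = 0.601 with an estimated correlation), which became 0.187 without control replicate 1, 0.0819 without control replicate 3 and 0.0591 without transport replicate 1. Proteasome genes were higher as a group, with 31 of 36 log2 fold changes positive (median 0.21) and psma7 alone called, from 55.1 ± 0.365 to 74.4 ± 2.02 FPKM. None was called when adjusted over the list alone. The camera adjusted p was 0.00850 (adjusted p = 0.717 with an estimated correlation), and it was 0.146, 0.0904 and 0.0649 without control replicate 1, control replicate 3 and transport replicate 3. Oxidative phosphorylation genes, encoding the respiratory chain, had 46 of 49 positive values (median 0.24) and no called member, over all genes or over the list alone. The smallest p was that of ndufa1, at 68.8 ± 3.73 and 96.6 ± 11.8 FPKM. Camera gave an adjusted p of 0.00166 (adjusted p = 0.717 with an estimated correlation), 0.0978 without control replicate 1 and 0.0649 without transport replicate 3.

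Interferon response genes, which act against viruses, were higher as a group. Of 35 tested, 7 rose and none fell, 15 rose when adjusted over the list alone, and the median log2 fold change was 0.42. Beside irf1, the DNA sensor gene cgas rose from 31.8 ± 5.31 to 54.2 ± 3.59 FPKM, helz2 from 9.18 to 18.3 FPKM, and usp18, a negative regulator of interferon signalling, from 10.293 to 21.9 FPKM. For this list camera gave an adjusted p of 3.06e-07 (adjusted p = 0.333 with an estimated correlation). The inflammation list as a whole did not pass (camera adjusted p = 0.130), with 6 of 45 members higher, 3 lower and a median of 0.03, whose sign turned under scaling of FPKM to equal sums, TMM scaling of FPKM and quantile normalization. Adjusted over the list alone, 7 were higher and 5 lower. The itaconate synthesis gene acod1 rose from 1.27 to 5.93 FPKM and inducible nitric oxide synthase, nos2, fell from 257 ± 116 to 65.9 ± 15.0 FPKM. In the list of neutrophils and macrophages 4 of 23 members rose and 2 fell, 7 and 6 when adjusted over the list alone (camera adjusted p = 0.345). The lysozyme gene lyz rose from 20.9 ± 3.74 to 55.0 ± 3.01 FPKM and ctsc fell from 66.8 to 40.0 FPKM. Complement and coagulation had 1 called member of 12, c7, against 10 negative values and a median of -0.69, with 1 higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.360).

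**Figure D2:**
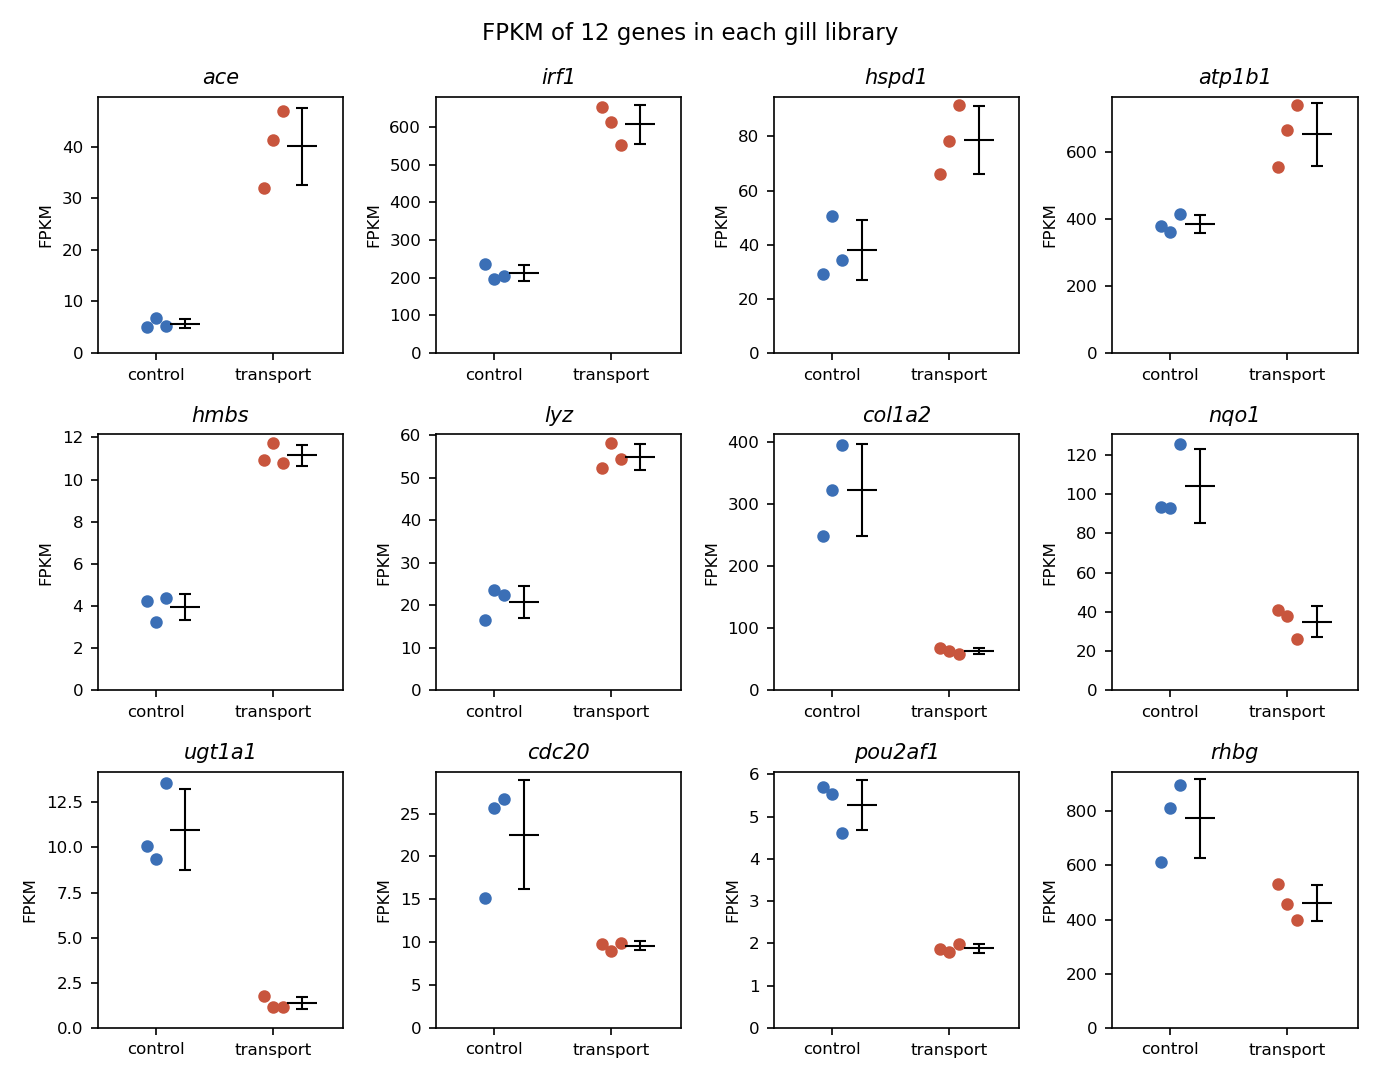
FPKM of 12 genes in each control and transport library (1 dot per library), with the mean and SD of the 3 libraries of a group beside the dots as a bar. In each panel the dots of the groups do not overlap, as for irf1 (mean 213 against 607 FPKM) and col1a2 (321 against 63.3 FPKM).

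Cell cycle genes fell together and had the smallest p of any list by camera with the preset correlation, while keratins and epithelium had the smallest by fry (adjusted p = 0.00328, against 0.0284 for cell cycle). Of 88 tested, 31 fell and none rose, 67 fell and 1 rose when adjusted over the list alone, and 85 of the 88 log2 fold changes were negative with a median of -0.71. The mitotic genes cdc20, an activator of the anaphase-promoting complex, and kif20a, a kinesin of cytokinesis, fell from 22.5 ± 6.37 to 9.58 ± 0.527 and from 10.4 ± 2.60 to 4.20 ± 0.456 FPKM. The replication gene mcm10 (log2 fold change -1.25) and the spindle midzone gene prc1 (-1.26) fell alike. With camera the list had an adjusted p of 2.96e-25 (adjusted p = 0.370 with an estimated correlation).

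Extracellular matrix genes fell as a group, with 13 of 43 lower and none higher, 20 lower when adjusted over the list alone, and a median log2 fold change of -0.65. Besides col1a2, the collagen gene col17a1 fell from 2.53 ± 1.23 to 0.577 ± 0.0757 FPKM. The small proteoglycan genes bgn and ogn fell from 1.46 to 0.227 and from 1.61 to 0.480 FPKM. Camera gave an adjusted p of 1.32e-12 (adjusted p = 0.333 with an estimated correlation). Cartilage and bone genes were lower as a group by camera, with 11 of 18 log2 fold changes negative and 7 positive (median -0.34). Of the 18, 4 fell, also 4 when adjusted over the list alone. These were phex, a phosphate-regulating peptidase gene (10.297 ± 2.13 to 2.45 ± 0.406 FPKM), col10a1 (74.1 ± 14.4 to 33.4 ± 5.41 FPKM), col11a1 and chad. Camera put the list at an adjusted p of 0.0225 (adjusted p = 0.584 with an estimated correlation), and 0.0521, 0.122 and 0.0649 without control replicate 2, control replicate 3 and transport replicate 3.

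The list of keratins and epithelium was lower as a group, with 9 of 21 members falling and 2 rising, 10 and 4 when adjusted over the list alone, and a median of -0.48. The basal epithelial regulator gene tp63 fell from 71.3 ± 9.45 to 42.9 ± 2.15 FPKM and anxa1 from 1019 ± 122 to 732 ± 42.3 FPKM, while the cornified envelope gene evpl rose from 39.8 ± 16.9 to 104 ± 2.61 FPKM and the transcription factor gene grhl1 from 67.7 to 95.6 FPKM. By camera the group had an adjusted p of 0.00161 (adjusted p = 0.333 with an estimated correlation). In the list of mucus and goblet cells 1 of 18 members rose and 2 fell (camera adjusted p = 0.251), among them agr2, a chaperone of mucin folding, from 291 ± 104 to 82.1 ± 17.0 FPKM. Of 35 tight junction genes pard3 alone was called, with a log2 fold change of -0.64 (camera adjusted p = 0.574).

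B-cell genes fell as a group, with 4 of 14 lower, also when adjusted over the list alone, and 13 of 14 values negative (median -0.51). The coactivator gene pou2af1 fell from 5.27 ± 0.589 to 1.88 ± 0.101 FPKM, the antigen receptor gene cd79a from 14.9 ± 2.01 to 7.19 ± 0.758 FPKM, bank1 from 7.34 to 3.16 FPKM, and the lineage regulator gene pax5 from 1.90 to 0.847 FPKM. The list test, camera, gave an adjusted p of 0.000270 (adjusted p = 0.333 with an estimated correlation). The lists of the other blood, immune, vascular, sensory and muscle cells did not pass camera. T cells and natural killer cells had 1 called gene of 19, tagap, which fell from 82.1 to 53.9 FPKM (adjusted p = 0.739). Antigen presentation had 1 called member of 36, with lgmn at 126 ± 17.3 and 87.7 ± 10.11 FPKM not called (adjusted p of the list = 0.528). Of 25 erythrocyte genes 3 rose, among them the heme synthesis gene hmbs, from 3.96 ± 0.617 to 11.2 ± 0.508 FPKM, and the mitochondrial iron importer gene slc25a37, from 4.47 to 9.08 FPKM (camera adjusted p = 0.528, with a list median of -0.21 against a test direction of higher). Without control replicate 2 the erythrocyte list passed (camera adjusted p = 0.0479). Endothelium and pillar cells had 1 called gene of 27, flt4, which fell from 2.35 to 0.860 FPKM (adjusted p = 0.391). Chemosensory and neuroendocrine cells had 1 of 18, the myelin gene mpz, which fell from 7.87 to 3.81 FPKM (adjusted p = 0.405). None of 35 skeletal muscle genes was called (camera adjusted p = 0.798), and hhatl, the member with the smallest p, stood at 0.967 ± 0.802 and 0.263 ± 0.0208 FPKM. The skeletal muscle list passed when control replicate 1 (adjusted p = 0.000750) or transport replicate 1 (0.0285) was left out.

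Immediate early genes, which respond within minutes to stimuli, were lower as a group by camera (median log2 fold change -0.63). Of their 16 values 11 were negative and 5 positive. Adjusted over the list alone, 6 fell and 1 rose, and over all genes 2 fell. These were nr4a3, from 5.36 ± 0.769 to 2.45 ± 0.210 FPKM, and klf6, from 53.4 ± 8.86 to 31.8 ± 2.71 FPKM. In the camera test this list had an adjusted p of 0.00771 (adjusted p = 0.584 with an estimated correlation), and 0.0685 without control replicate 2 and 0.0729 without transport replicate 3. Circadian clock genes were lower as a group, with 2 of 12 falling, 4 falling and 1 rising when adjusted over the list alone, and a median of -0.32. The called members were bhlhe40, a transcriptional repressor gene (64.7 ± 7.73 to 28.9 ± 6.18 FPKM), and timeless, which also acts at replication forks (2.61 to 1.41 FPKM). Camera returned an adjusted p of 0.0225 (adjusted p = 0.333 with an estimated correlation), and 0.0534, 0.0685 and 0.0989 without control replicates 1, 2 and 3.

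Genes of the classical stress responses outside protein folding moved both ways. The glucocorticoid response list had 4 of 25 lower and none higher, and 9 lower and 1 higher when adjusted over the list alone (camera adjusted p = 0.0928, and 0.0274 without control replicate 1), among them the mineralocorticoid receptor gene nr3c2, from 2.33 to 1.09 FPKM, and foxo1, from 4.61 to 2.51 FPKM. The glucocorticoid receptor gene nr3c1 was at 11.2 ± 2.14 and 10.15 ± 2.17 FPKM, and its target fkbp5 at 181 ± 52.0 and 272 ± 62.9 FPKM, neither of them called (edgeR adjusted p = 0.666 and 0.209). Of 27 hypoxia response genes 2 rose and 4 fell (camera adjusted p = 0.0864, and 0.0369 without transport replicate 2), with egln3 falling from 4.84 to 2.39 FPKM beside bhlhe40. The oxygen-sensing factor gene hif1a was at 9.81 ± 0.840 and 8.95 ± 0.2996 FPKM (edgeR adjusted p = 0.431). Of 44 antioxidant defence genes 2 rose and 1 fell (camera adjusted p = 0.739). The quinone reductase gene nqo1 fell from 104 ± 18.8 to 35.0 ± 7.90 FPKM and the glutathione synthesis gene gclm rose from 10.9 ± 2.89 to 20.2 ± 0.294 FPKM, while hmox1 was at 13.6 ± 4.28 and 11.8 ± 2.53 FPKM (edgeR adjusted p = 0.701). Apoptosis had 1 of 39 higher and 2 lower, tp63 and the kinase gene map3k5, which fell from 9.96 to 6.72 FPKM (camera adjusted p = 0.462). Autophagy and lysosome had foxo1 as the 1 called gene of 39 (adjusted p = 0.414). Xenobiotic metabolism had 1 of 11 higher, the efflux pump gene abcb1 (0.213 ± 0.121 to 1.063 ± 0.0651 FPKM), and 2 lower, ugt1a1 among them (camera adjusted p = 0.0874, and 0.0341 without control replicate 3).

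Ion transport, nitrogen handling, lipid and sugar metabolism gave no called list, but several genes changed. The sodium pump subunit gene atp1b1 rose from 384 ± 27.9 to 651 ± 93.1 FPKM, as 1 of 2 higher members among 30 in the ionocyte and ion transport list (camera adjusted p = 0.360). Of 22 genes of ammonia and nitrogen handling 3 rose and 1 fell (adjusted p = 0.146). The ammonia channel gene rhbg fell from 775 ± 146 to 462 ± 65.5 FPKM, rhcg was at 147 ± 31.9 and 146 ± 29.1 FPKM (edgeR adjusted p = 0.970), and the urea cycle gene otc rose from 3.90 ± 0.407 to 11.7 ± 3.29 FPKM. Cholesterol and fatty acid synthesis had 2 of 33 lower (camera adjusted p = 0.794), the acetyl-CoA supply gene acly, from 26.6 ± 7.51 to 10.9 ± 0.526 FPKM, and srebf1, from 15.3 to 11.1 FPKM. Fatty acid oxidation had 1 of 34 higher and 1 lower (adjusted p = 0.570), the lipid droplet gene plin2, from 11.9 to 33.6 FPKM, and acsl4, from 15.8 to 8.41 FPKM. No member of the glycolysis and gluconeogenesis list of 25 was called (adjusted p = 0.887), with the lactate transporter gene slc16a1 at 6.07 ± 1.37 and 9.46 ± 0.382 FPKM. Of 68 cytosolic ribosomal protein genes rpl22l1 alone was called, from 192 ± 31.1 to 321 ± 34.0 FPKM (camera adjusted p = 0.0570, and 0.0322 without transport replicate 1), and 62 of the 68 values were positive.

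In all, camera called 12 of the 35 lists, 5 higher and 7 lower, none of them with an estimated correlation. Limma's fry called 10 lists, of which 7 were among the 12. It did not call unfolded protein response (fry adjusted p = 0.0663), oxidative phosphorylation (0.191), proteasome (0.242), cartilage and bone (0.130) or immediate early genes (0.175), and it called hypoxia response (0.0284), mucus and goblet cells (0.0333) and xenobiotic metabolism (0.0333), which camera did not. Adjusted over the list alone, the higher and lower members were 2 and 7 for hypoxia response, 5 and 2 for ammonia and nitrogen handling, 2 and 3 for xenobiotic metabolism, 1 and 3 for mucus and goblet cells, 4 and 1 for erythrocytes, 3 and 2 for fatty acid oxidation, 2 and 1 for endothelium and pillar cells, and 2 and 1 for ionocyte and ion transport. The test direction and the median had opposite signs for erythrocytes and for cholesterol and fatty acid synthesis, and the mean and the median for those of erythrocytes, cholesterol and fatty acid synthesis, antioxidant defence, fatty acid oxidation and skeletal muscle. The small medians of glycolysis and gluconeogenesis, tight junction, inflammation, and neutrophils and macrophages changed sign under at least 1 other scaling.

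**Figure D3:**
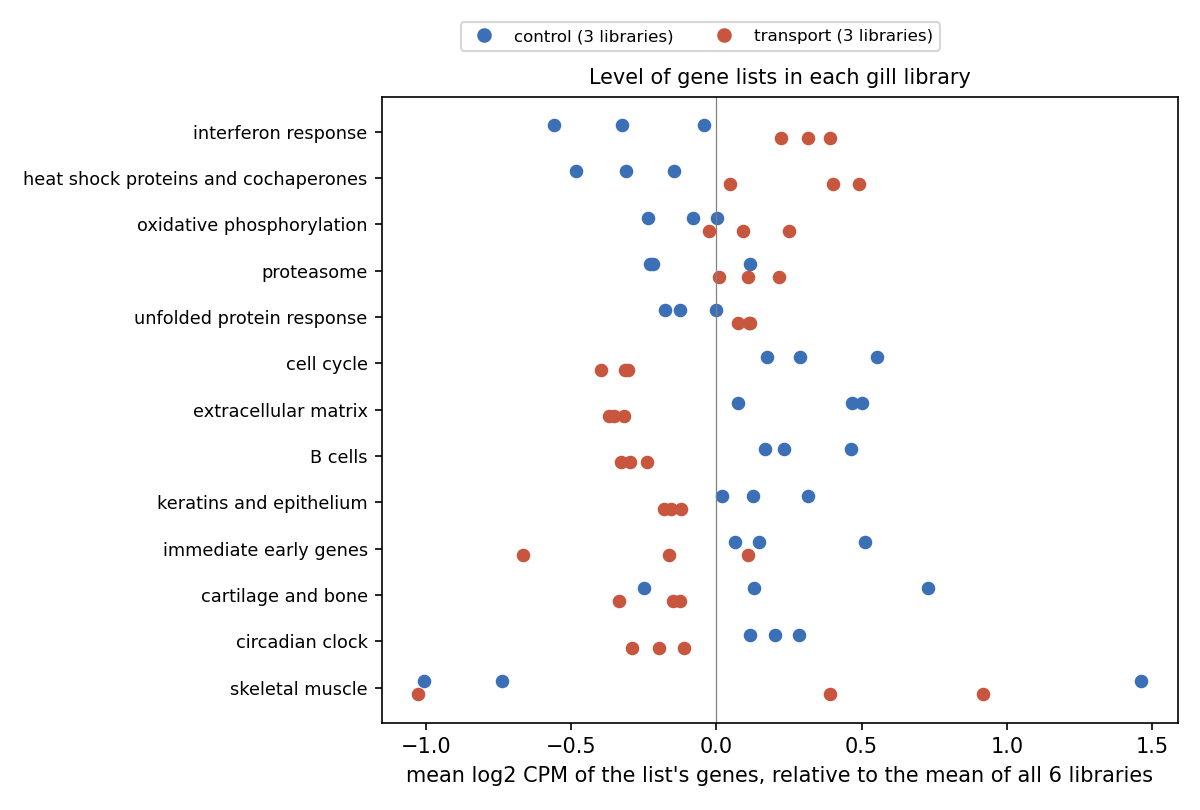
Mean log2 CPM of the genes of the 12 called lists and of skeletal muscle in each library, relative to the mean of all 6 libraries, with 1 dot per library. The groups are separate for cell cycle (0.17 to 0.55 in controls, -0.40 to -0.30 after transport) but not for skeletal muscle, oxidative phosphorylation, proteasome, immediate early genes, or cartilage and bone.

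Terms of the deposited annotation were over-represented among higher genes mainly for ribosome production. The nucleolus term held 36 called genes against 8.23 expected (adjusted p = 1.42e-10, Fisher's exact test), rRNA processing 15 against 2.12, and ribosome biogenesis 13 against 1.69. Response to virus held 7 against 1.03, of which 4 were interleukin-1 beta copies, and the KEGG pathway of NOD-like receptor signalling 34 against 13.6. Among lower genes, collagen trimer held 18 against 2.14 (adjusted p = 2.41e-09), intermediate filament 13 against 1.63, cellular response to xenobiotic stimulus 8 against 0.942, and the MCM complex, the replicative helicase, 4 against 0.398. The KEGG pathways regulation of actin cytoskeleton and focal adhesion held 35 against 12.3 and 32 against 12.4. In all, 51 of 3620 term tests passed, 21 for higher and 30 for lower genes. That number was 61, 23, 13, 11, 0 and 7 without control replicates 1, 2 and 3 and transport replicates 1, 2 and 3.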

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

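Library-size scaling without TMM and counts divided by 4 were chosen after the results were seen, and every other setting was fixed beforehand. With counts divided by 4 fewer genes met the count filter, 18250 against 20771, and edgeR called 1675. Of the 1389 main calls, 1374 were fitted there and all 1374 stayed called. No setting reversed a called list or any of the 77 called genes named in the report. The lists of heat shock proteins and cochaperones, interferon response, keratins and epithelium, B cells, extracellular matrix and cell cycle passed in 26 of 27 alternatives each, all but camera with an estimated correlation, under which 0 lists passed. Oxidative phosphorylation passed in 23, proteasome in 22, immediate early genes in 21, circadian clock in 17 and unfolded protein response in 15 of 27, and cartilage and bone in 15 of 25.

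With all 6 libraries kept, the number of called genes moved most with the replicate block, DESeq2 and array weights. With the replicate block edgeR called 14 genes, 9 higher and 5 lower, all 14 of at least 2-fold, among them ace and irf1, and 0 terms passed. With the same block limma called 121 genes (72 higher, 49 lower, 117 of at least 2-fold) and 9 terms. The replicate numbers gave no sign of pairing the libraries. The deviations of equally numbered control and transport libraries correlated at -0.0735, -0.0296 and -0.0441. The block also takes up degrees of freedom. DESeq2 called 3238 genes (1545 higher, 1693 lower, 1306 of at least 2-fold) and 102 terms. In the simulation it made more false calls than edgeR. That simulation took its dispersions from edgeR and changed few genes, so it does not give the share of false calls here. Array weights in limma called 3205 genes (1813 higher, 1392 lower) and 108 terms. The direction with more calls depended on the setting. Higher genes made up 48.3% of the calls in the main fit, 47.7% by DESeq2 and 52.8% by edgeR without TMM. With limma they made up 56.4% on log2(FPKM + 1) and 49.6% after quantile normalization. With genes of at least 2-fold change alone, 25 terms passed. At a mean FPKM of at least 5 the genes of at least 2-fold change numbered 439 by edgeR and 356 by limma, and without a filter limma called 413 such genes and 429 lower genes in all. The first principal component held 38.3% of the variance with a pseudocount of 0.1 and 49.9% at a mean FPKM of at least 5. The cause of these changes was not tested.

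Leaving out each library gave from 3 to 1498 called genes, from 2 to 659 higher and from 1 to 839 lower, from 3 to 816 of at least 2-fold, and from 0 to 61 terms, with the lowest value always without transport replicate 2 and the highest without control replicate 1. The first principal component ranged from 42.2% to 55.4%. Of the uncalled lists whose direction changed, camera adjusted p ranged over these fits from 0.232 to 0.882 for T cells and natural killer cells, from 0.0685 to 0.852 for antigen presentation, from 0.353 to 0.864 for antioxidant defence, and from 0.339 to 0.893 for cholesterol and fatty acid synthesis. It ranged from 0.383 to 0.966 for glycolysis and gluconeogenesis, from 0.165 to 0.919 for neutrophils and macrophages, and from 0.000750 to 0.930 for skeletal muscle. The log2 fold change ranged from -0.35 to 0.0090 for nr3c1 and from -0.18 to 0.14 for rhcg.

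Other reversed results concerned uncalled lists and rhcg, whose edgeR log2 fold change of -0.018 is close to 0. Complement and coagulation reversed at a mean FPKM of at least 1 (camera adjusted p = 0.880), and inflammation at a mean FPKM of at least 5 with edgeR (0.569) and limma (0.421). Erythrocytes reversed with limma on log2(FPKM + 1) (0.927), pseudocounts of 0.1 (0.957) and 0.5 (0.949), a mean FPKM of at least 5 (0.706), FPKM rescaled to equal sums (0.964), TMM scaling of FPKM (0.968), the replicate block (0.927), no trend (0.927), robust fitting (0.927) and array weights (0.919). Cholesterol and fatty acid synthesis reversed with limma at pseudocounts of 0.1 (0.957) and 0.5 (0.993), without a filter (0.812), with the block (0.942) and with array weights (0.918). Skeletal muscle reversed with limma at a mean FPKM of at least 5 (0.966), and glycolysis and gluconeogenesis with array weights (0.729). The log2 fold change of rhcg was 0.0030 with limma on log2(FPKM + 1), and equally without a filter, at a mean FPKM of at least 5, with the block, without trend and with robust fitting. It was 0.00305 and 0.00303 with pseudocounts of 0.1 and 0.5, 0.0211 with array weights and 0.00365 by edgeR without TMM.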

Other observations

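The tests of 1 library, of lymphocytes and of the clock, and all families and locus numbers named here, were chosen after their results were seen, while the trend, on or off and split tests were written beforehand. No list of genes controlled by the aryl hydrocarbon receptor was tested, and the fixed xenobiotic metabolism list did not pass (camera adjusted p = 0.0874), but all 3 tested cytochrome P450 1 genes were lower, LOC113652605 (CYP1A1-like) from 74.8 ± 33.5 to 12.3 ± 3.68 FPKM and LOC113661120 (CYP1B1-like) from 13.2 ± 2.42 to 2.11 ± 0.510 FPKM. Of the genes annotated as this receptor, LOC113655495 fell from 3.27 to 0.507 FPKM, and the more abundant LOC113646263 and LOC113651854 fell less (55.3 to 41.2 and 10.35 to 7.21 FPKM, log2 fold changes -0.44 and -0.54). The gene ahr itself, at 6.31 and 7.55 FPKM, and LOC113651882 were not called. Of 23 genes similar to up-regulator of cell proliferation 14 rose (median log2 fold change 2.11), and of 6 interleukin-1 beta genes 4 rose (median 2.69).

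Of 68 collagen genes 25 fell and 2 rose (median log2 fold change -0.86). The 25 matrix metalloproteinase genes, not tested as a list, went both ways, 5 higher, 2 lower and the others uncalled (median 0.30), with mmp11 falling from 93.6 to 21.8 FPKM and LOC113656210 (MMP9-like) rising from 15.9 to 106 FPKM. LOC113649589 and LOC113657363, annotated as similar to the alpha and gamma subunits of thread biopolymer filaments, fell from 79.6 to 16.8 and from 82.3 to 22.5 FPKM. Of 40 class I histocompatibility genes 6 rose and 1 fell, with a median of -0.19, and of 13 class II genes 2 fell (median -0.63). The abundant class II gamma chain gene LOC113654954 fell from 5718 ± 912 to 3062 ± 231 FPKM. Nucleolar genes that rose included rpf2, from 17.8 to 40.5 FPKM, and gnl3, from 13.99 to 31.7 FPKM. Reads may be shared among the near-identical copies of these families, so a family is safer ground than a copy, and for the on or off genes this was tested below (20% with an opposite copy).

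The fall of cell cycle genes was weighed against 3 other explanations. A trend of fold change with gene length or level was argued against, as the list median was -0.73 after that trend was subtracted and -0.71 before (bootstrap SD 0.049). No library alone set the change, since the leave-one-out median nearest to 0 was -0.60, without control replicate 2. Fewer lymphocytes of all kinds could not be excluded, although genes of T cells and natural killer cells did not fall. Their mean change was -0.00075 (SE 0.20), against -0.68 (SE 0.12) for cell cycle genes. The difference of 0.68 (SE 0.30) was only just past 2 SE with all libraries. It was not past 2 SE without control replicate 2 (0.43, SE 0.29) or control replicate 3 (0.65, SE 0.52). The scale of this test was changed to edgeR log CPM after a first value had been seen, with the same verdict. By the test's own rule that verdict was against this explanation, but it is not kept here because it hung on single libraries. B-cell genes changed by -0.58 (SE 0.094).

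Some genes were on in 1 group and off in the other, at an FPKM of at most 0.1 and at least 1. There were 8, against at most 3 in any other split of the libraries, which exceeds 2 times that number by less than the spread of 4.47, so differences between single fish stay possible. That spread term was added after the values had been seen, and before it the result had been read as an argument against this explanation. They included LOC113651616, an aerolysin-like pore-forming protein gene (at most 0.03 FPKM in controls, 5.67, 7.24 and 10 FPKM after transport), and LOC113641678, similar to C4b-binding protein (0 in controls, 3.81, 6.88 and 5.98 FPKM). Reads assigned to another copy stay open too, as 20% (1 of 5) had an opposite copy against 14.4% of 617 other genes (Fisher's exact p = 0.544). LOC113649539 and c7, described above, were also among the 8 genes, so both explanations stay open for them as well.

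The lower clock genes might reflect another time of day at sampling, which is not given in the sources used here. Clock activators had a median log2 fold change of -0.39 (6 genes) and repressors and outputs -0.44 (17 genes), a difference of 0.0454 with a spread of 0.28. Of the activators 5 were lower, 1 was higher and 0 were called. Of the repressors and outputs 16 were lower, 1 was higher and 5 were called. Another time of day would likely move the arms apart, but the test cannot tell. Its spread term was also added after the value was seen, before which the test had been read as an argument against. Sampling of controls and transported fish at stated hours would settle it.

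All 10 splits of the 6 libraries into 3 and 3 were tested in the same way, a number too small for a share under 0.1. Only 1 split, the real one, gave as many as 1389 genes, 675 genes of at least 2-fold and 51 terms, each against 0 in every other split. In the other splits a group difference would add to the spread within each side, which lowers the number of calls. With 0 called genes no term can pass, so these 0 values are not separate support for the real split. For gene lists 2 of the 10 splits gave as many as the real 12. The other, with 14 lists, put control replicate 1 with transport replicates 2 and 3, the libraries rich in skeletal muscle, whose list had a camera adjusted p of 1.25e-62 there. The real split had the smallest p for 7 of the 12 called lists, heat shock, interferon, keratins, B cells, extracellular matrix, cell cycle and circadian clock. Of these, keratins and circadian clock passed in no other split, but cell cycle passed in 6 others (lowest adjusted p = 1.07e-13), heat shock and interferon in 5 each, extracellular matrix in 4 and B cells in 2. Oxidative phosphorylation and proteasome had their smallest adjusted p (1.67e-09 and 2.01e-11) where control replicates 1 and 3 stood with transport replicate 1. Immediate early genes (2.88e-05), cartilage and bone (0.00813) and unfolded protein response (0.0157) also had a smaller adjusted p in another split. The camera calls of these 5 lists weigh little beside the spread between libraries. Each other split put 2 libraries of a group with 1 of the other, so part of a group difference remained in it. Passes there can thus come from that remainder or from spread between libraries, and the splits cannot tell which. Passing camera alone does not settle this for heat shock, interferon, B cells, extracellular matrix or cell cycle.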
